A study of Mus musculus with 14 samples.

How the data were processed

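RNA was sequenced from 4 samples of sorted retinal cells of CD1 mice, and CUT&RUN was run on 10 samples of CD1 mouse retina. In CUT&RUN an antibody brings a nuclease to a bound protein, and the DNA released around it is sequenced. For the RNA samples, eyes were electroporated on the day of birth (P0) with plasmid DNA at 1 µg/µl, either a short hairpin construct against Bcor (shBCOR) or an empty vector with a fluorescent marker (control), per the labels. The eyes were collected at postnatal day 21, dissociated with Accutase for 30 minutes, and fluorescent cells were sorted after 10 to 15% of cells had been excluded as dead. Several sorts were pooled to reach 30000 to 70000 cells per replicate, with 2 replicates per group. The p-values of the RNA comparison therefore measure the spread between pools of sorted cells, and the labels do not say how many eyes or litters each pool held. Libraries were made from 3.0 to 5.1 ng of RNA after removal of ribosomal RNA, with a stranded random-primed kit and 15 PCR cycles. The CUT&RUN samples were BCOR and Otx2 at embryonic day 14 (E14), with 1 library each, and at P0 and in the adult, with 2 libraries each. The series text writes the second factor as Otx2/Crx, while the sample labels name Otx2; whether the antibody also binds CRX was not given in the sources used here.

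The RNA values were whole-number counts per RefSeq record as deposited, made by the authors with HTSeq, per the labels. The submitters' processing notes also name Trimmomatic, TopHat and DESeq2, and Bowtie2, MACS2 and deepTools, without versions or roles, and the builds mm10 and mm9. The strand setting of the counting, and how a read that lies in several records of a gene was treated, were not given in the sources used here. Each table held 45895 records, of which 45749 (99.7%) were matched to a gene symbol through a RefSeq gene table of assembly GRCm38.p6. Genes with a single record took 93.1% of all counts, and 46.4% of their 17349 records had a count in some library. Genes with several records took 6.39% of all counts, and 14.3% of their 28400 records had a count, so the level of a gene with several records is uncertain in these tables. Records without a symbol took 0.465% of the counts, nearly all of it in NR_046233, and 0 records of mitochondrially encoded genes were listed. Overlapping and antisense genes were likewise not told apart, since the strand setting is unknown.

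The CUT&RUN values were 10 peak lists called by the authors with MACS2 for each library separately, per the labels. For every peak the deposited lists gave a score, a fold (the ratio of signal to background at the summit), a −log10 p-value and a −log10 q-value, and the place of the summit. These are the authors' values for that peak in that library. They were used here to rank or filter peaks within a list and to measure distances between summits. For single regions the folds of several libraries are also given side by side. Those libraries differ in unknown ways in depth, so such folds are descriptive only. The control used in peak calling and the threshold were not given in the sources used here. The largest q-value differed between the deposited lists, at 0.0999 and 0.0996 for BCOR and Otx2 at E14, 0.248 in both adult BCOR lists and 0.0466 to 0.0496 in the other lists. Read depth of the CUT&RUN libraries is unknown, so the numbers of peaks of different libraries were not compared as measurements of binding. Chromosome names and peak ends were those of mm9, and coordinates are given on mm9, counted from 1. No genome or annotation of mm9 was used here. The planned comparisons of peaks with promoters, with the genes of the RNA fit, with the loci chosen in advance and with the Otx2 motif were therefore not analysed here.

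Samples were grouped by their titles. The deposited table of shBCOR replicate 2 carries another replicate number than its title; the title was followed, and the replicate block rests on it. The main tests, a first set of alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Further alternatives, the shares of Otx2 regions between stages and the tests of gene lists against each other were added after the data were seen. The RNA counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group, and the robust quasi-likelihood fit and F test of shBCOR against control. Benjamini-Hochberg adjustment ran over the 7921 records tested, and a record passed at an adjusted p under 0.05. The common biological coefficient of variation was 0.564. Gene lists were tested with camera of limma 3.58.1 on log2 CPM values (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the 23 of 29 lists that had at least 5 records tested. Camera with an estimated correlation and fry were alternatives. For each list the number of members that passed when adjusted over the list alone is also given. The lists covered rod, outer segment and cilium, cone, photoreceptor transcription factor and photoreceptor synapse genes; markers of bipolar, amacrine, ganglion and horizontal cells, Müller glia, astrocytes and oligodendrocytes, retinal pigment epithelium, microglia and macrophages, vessels and pericytes, red blood cells and lens; retinal stress and gliosis, interferon response, p53 and apoptosis, immediate early and unfolded protein response genes; the BCOR complex, Polycomb complexes, Polycomb-silenced regulators, retinal progenitors and the cell cycle; and oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins and mitochondrially encoded genes.

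Named genes were Bcor, then up to 12 called records per direction with at least a 2-fold change, a mean of at least 2 on the log2 CPM scale and both shBCOR libraries on the same side of both controls, then up to 4 called members of each list. Where no record of a direction passed, the 6 with the smallest p are given as values that did not pass. Members of lists that did not pass are examples, up to 4 per list by smallest unadjusted p, chosen after the data were seen. Some items that this rule named are not reported here. A fold against a group with no counts is a lower bound, computed with a floor of 3 counts over the group.

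Totals were 5107174 and 4973402 counts in the control libraries and 3173927 and 4093380 in the shBCOR libraries. On counts simulated from these libraries with 200 records changed, the edgeR test recovered 3.5% of 2-fold changes with 0 false calls, and 14.3% of those above 64 CPM. It recovered 39% of 4-fold changes with 3 false calls among 81, and 100% of those above 64 CPM. DESeq2 1.42.0, run as an alternative, made 6 calls on simulated counts with no change and 22 false calls among 48 at 2-fold. The simulated counts took the spread that edgeR had fitted to these libraries, which can favour edgeR. The share of false calls among DESeq2 calls on the real counts is therefore unknown. An equal-depth alternative thinned all libraries to 3173927 counts. Intervals and bounds cover counting error only, since PCR copies of a molecule were not told apart.

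Peaks on the 19 autosomes and X were compared with bedtools 2.31.1 through Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. An overlap of 1 bp counted as shared. For factors with 2 libraries, a region was a stretch of overlapping peaks that held a peak of each replicate. Shares have 95% Wilson intervals. Each share was set against 100 random placements of the regions on their own chromosomes, with a one-sided permutation p whose smallest value is 0.0099. Random placement also reaches stretches in which no peak could be called, so chance is a low bar. The odds ratio within the merged regions of all 10 lists is stricter. Those regions pool the stages, so places with peaks at other stages alone count as holding neither factor, which raises the odds ratio. On simulated lists with 25, 50 and 75% of regions planted on the other list, shares of 25.4, 50.1 and 75.0% were recovered, and 0 of 40 unrelated pairs passed. Alternatives changed the overlap required, took the upper 50% of each list by fold, took each replicate alone, or set all lists to the length of the shortest, 1374 peaks, by fold.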

Results

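Mouse retina was examined by RNA sequencing after knockdown of Bcor and by CUT&RUN for the proteins BCOR and Otx2 during development. BCOR is a transcriptional corepressor and a member of a variant Polycomb repressive complex. Otx2 is a homeobox transcription factor of photoreceptor and bipolar cells. For RNA, 2 control and 2 shBCOR libraries were made from fluorescent cells sorted at postnatal day 21 after electroporation at P0. The control libraries held 5107174 and 4973402 counts, and the shBCOR libraries held 3173927 and 4093380. Counts above 0 were found for 9525 and 9714 records in the controls and for 8128 and 8612 in the shBCOR libraries. At an equal depth of 3173927 counts these numbers were 9433, 9629, 8128 and 8569. The 10 most abundant records took 26.7 and 26.7% of the counts in the controls and 30.7 and 28.5% in the shBCOR libraries. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 13.1 between the controls and 17.8 between the shBCOR libraries, against 21.7 to 25.1 between groups. The Pearson correlation of log2 CPM across records was 0.893 between the controls and 0.841 to 0.855 between groups. Between the shBCOR libraries it was 0.832, so by this measure they were no more alike than libraries of different groups.

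The RNA comparison addressed how retinal cells change when BCOR is lowered. Bcor itself, the targeted gene, had 6 records in the tables, and 5 of them had no counts in any library. The remaining record, NR_045434, had 20 and 8 counts in the controls and 0 and 13 in the shBCOR libraries. Its log2 fold change was −0.63 ± 2.44 (SE, n = 2 per group), with an adjusted p of 0.996 in edgeR. A lower level of Bcor was therefore not detectable in these counts, and the labels of the shBCOR libraries were not checked by their target. Genes with several records hold few counts in these tables (14.3% of their records had a count, against 46.4% for genes with a single record), so the level of Bcor is uncertain in them. The value turned to 0.13 without control replicate 1 and to 0.34 without shBCOR replicate 1. It was −1.14 without control replicate 2 and −6.58 without shBCOR replicate 2, where the remaining shBCOR library had 0 counts, so that the size of this fold has no meaning.

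In the shBCOR cells the photoreceptor genes Rp1 and Impg2 rose, and Nefm, Kif5c and Chd3, genes of neurons and chromatin, fell. Rp1 (NM_011283), a microtubule-binding protein of the photoreceptor outer segment, rose 1.66-fold, with a log2 fold change of 0.73 ± 0.07 (SE, n = 2 per group; adjusted p = 0.0187, edgeR). Impg2 (NM_174876), a proteoglycan of the matrix between photoreceptors, rose 1.74-fold (0.80 ± 0.09, adjusted p = 0.0377). Among the records that passed, Nefm (NM_008691), the medium neurofilament chain, fell most, with 593 and 631 counts in the controls and 25 and 49 in the shBCOR libraries, 10.8-fold lower (−3.43 ± 0.33, adjusted p = 0.0230). Chd3 (NM_146019), a chromatin remodeller of the NuRD complex, had 3753 and 3844 counts in the controls and 662 and 929 in the shBCOR libraries, 3.07-fold lower (−1.62 ± 0.13, adjusted p = 0.0177). Kif5c (NM_008449), a neuronal kinesin, fell 2.97-fold, from 7085 and 7370 counts to 1464 and 1622 (−1.57 ± 0.13, adjusted p = 0.0177).

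**Figure D1:**
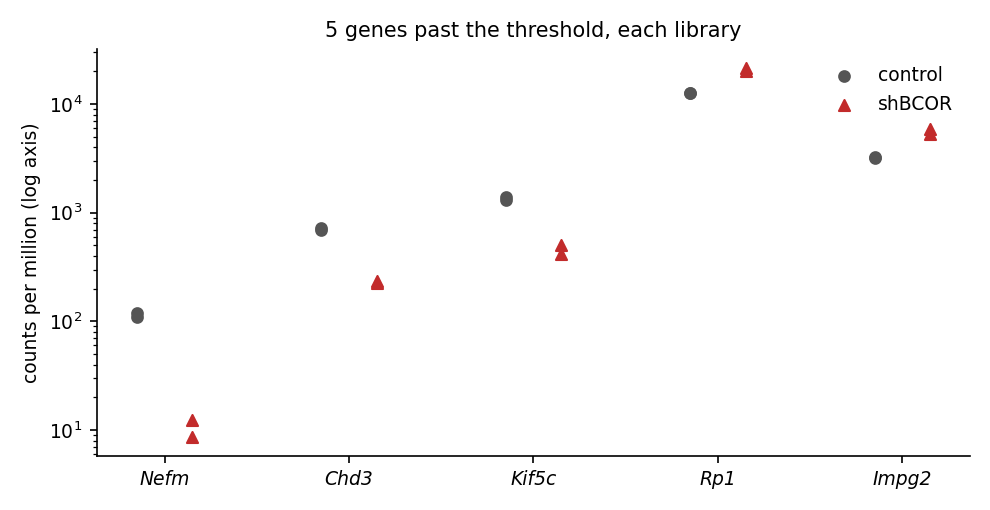
Counts scaled to CPM on a log axis for 5 genes that passed the edgeR test, with each point a library (grey circles, control; red triangles, shBCOR). Both shBCOR libraries lie below both controls for Nefm, Chd3 and Kif5c, and above both for Rp1 and Impg2.

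In all, 7 of the 7921 records tested with edgeR passed, 3 higher and 4 lower, and 703 had an unadjusted p under 0.05, 323 higher and 380 lower. In 41.9% of the records tested both shBCOR libraries lay on the same side of both controls, 1471 higher and 1844 lower, where chance gives 33.3%. No record that passed was higher by 2-fold or more. The 6 with the smallest p in that class, given as values that did not pass, were Pla2g5, AI506816, Lims1, AW549877, Sec22a and Tcf24. Pla2g5, a secreted phospholipase, had 0 counts in both controls and 59 and 69 in the shBCOR libraries, at least 66.4-fold higher (adjusted p = 0.0955). AI506816 had 0 counts in both controls and 28 and 117 (at least 75.2-fold, adjusted p = 0.123), and Lims1, an adaptor of cell adhesion, had 0 and 24 and 81 (at least 54.5-fold, adjusted p = 0.183). Pla2g5 and AI506816 are genes with 2 records, and Lims1 has 6. Their folds are those of single records, and the level of each gene is uncertain. The bHLH factor Tcf24 had 10 and 23 counts in the controls and 74 and 105 in the shBCOR libraries, with a log2 fold change of 3.05 (adjusted p = 0.207). AW549877 and Sec22a had log2 fold changes of 1.13 and 1.07 (adjusted p = 0.204 and 0.207).

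Without control replicate 1 the calls of Rp1 and Impg2 ended, with log2 fold changes of 0.73 and 0.81 (adjusted p = 0.120 and 0.147), as they did without control replicate 2, with 0.73 and 0.78 (0.0827 and 0.113). With an offset for gene span, tried after seeing the data, Chd3 and Rp1 alone stayed past the threshold, while Nefm had −3.25 and Kif5c −1.47 (adjusted p = 0.0528 for both) and Impg2 0.83 (0.0581). DESeq2 called 405 records, 195 higher and 210 lower, the 7 among them.

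The lists of outer segment and cilium genes and of rod genes were higher in the shBCOR cells as groups, with medians of less than 2-fold. Of 21 records of outer segment and cilium genes, 3 rose, 0 fell and 18 did not pass, with a median log2 fold change of 0.48 (camera adjusted p = 0.000297; adjusted p = 0.613 with an estimated correlation). Adjusted over the list alone, 11 were higher and 0 lower. Beside Rp1 and Impg2, the retinoid transporter Abca4 had a log2 fold change of 0.58 (adjusted p = 0.0681). Rp1 had 3 records tested, and those other than NM_011283 did not pass. Of 23 records of rod genes, 0 passed over all records, and the median was 0.33 (camera adjusted p = 0.000661; adjusted p = 0.613 with an estimated correlation). Adjusted over the list alone, 10 rod records were higher and 0 lower. Both shBCOR libraries lay above both controls for 18 of these 23 records. Gucy2f, a guanylate cyclase of the phototransduction cascade, had a log2 fold change of 0.69 (adjusted p = 0.0836), the kinase Grk1 had 0.46 (0.0836), the phosphodiesterase subunit Pde6a had 0.39 (0.102) and Rgs9 had 0.39 (0.172). The call of the rod genes was also lost with fry in a single direction (adjusted p = 0.262).

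Cone genes, photoreceptor transcription factors and photoreceptor synapse genes did not pass the test as groups. Of 13 cone records 0 passed, the median log2 fold change was −0.14 while the mean was 0.02, and the camera adjusted p was 0.917. Adjusted over the list alone, 1 was higher, the potassium channel subunit Kcnv2 (0.54, adjusted p = 0.112 over all records). Photoreceptor transcription factors had a median of 0.28 over 16 records (camera adjusted p = 0.158) with 0 members passing, and Neurod1 had 0.33 (adjusted p = 0.55). Synapse genes of photoreceptors had a median of 0.22 over 26 records (camera adjusted p = 0.164). None of these 26 passed over all records, and adjusted over the list alone 3 were higher and 1 lower. Lrit1, Dmd and Unc13b had log2 fold changes of 0.55, 0.50 and 0.40 (adjusted p = 0.129, 0.147 and 0.271), while Cplx3, a complexin of ribbon synapses, had −0.90 (adjusted p = 0.0836).

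Markers of inner retinal neurons were lower in the shBCOR cells as groups. Of 12 records of ganglion and horizontal cell markers, 0 rose, 1 fell and 11 did not pass, with a median log2 fold change of −1.51 (camera adjusted p = 0.00291; adjusted p = 0.613 with an estimated correlation). Adjusted over the list alone, 4 were lower and 0 higher. The member that fell was Nefm, and the neurofilament chains Nefh and Nefl had −1.76 (adjusted p = 0.068) and −1.72 (0.0955). Of 11 records of amacrine cell markers 0 passed over all records, with a median of −0.80 (camera adjusted p = 0.00412; adjusted p = 0.613 with an estimated correlation). Adjusted over the list alone, 4 amacrine records were lower and 0 higher. Gad1 and Gad2, which make GABA, had −2.66 and −2.33 (adjusted p = 0.155 and 0.19), and C1ql2 had −2.64 (0.353). Of 19 records of bipolar cell markers 0 passed over all records or adjusted over the list alone, with a median of −0.52 (camera adjusted p = 0.00884; adjusted p = 0.613 with an estimated correlation). Both shBCOR libraries lay below both controls for 12 of these 19. Grm6, the glutamate receptor of ON bipolar cells, had −1.33 (adjusted p = 0.265), Bhlhe22 had −1.58 (0.291), Cabp5 had −0.91 (0.318) and Lhx4 had −1.69 (0.457). These calls ended in part when single libraries were left out: without control replicate 2 all 3 ended (camera adjusted p = 0.157, 0.06 and 0.236), without control replicate 1 the amacrine and bipolar calls ended (0.38 and 0.168), without shBCOR replicate 1 the bipolar call (0.54) and without shBCOR replicate 2 the amacrine call (0.0516). With fry in a single direction the ganglion and bipolar calls also ended (adjusted p = 0.238 and 0.343).

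**Figure D2:**
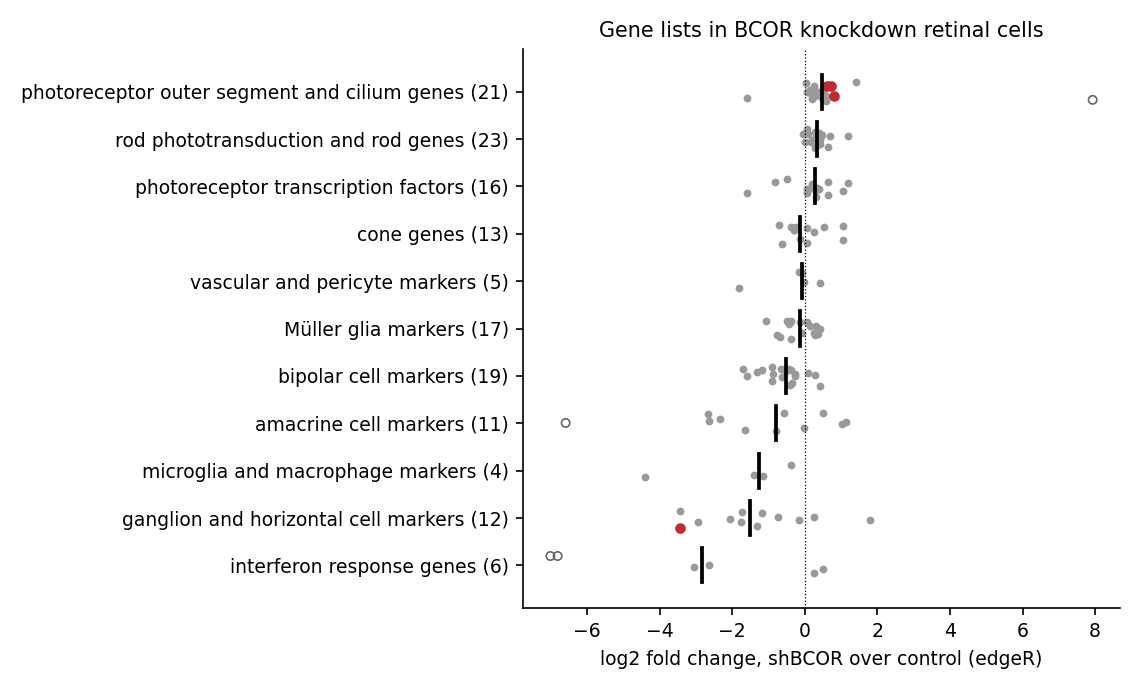
Log2 fold changes (edgeR, shBCOR over control) of the records tested in 11 gene lists, with the number of records in brackets; red points passed over all records, open circles had 0 counts in both libraries of a group, and black bars are medians. The medians run from 0.48 for outer segment and cilium genes to −2.84 for interferon response genes.

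The other cell types that a sort of retinal cells could hold did not pass the test as groups. Müller glia markers had a median log2 fold change of −0.12 over 17 records (camera adjusted p = 0.917), with 0 passing. Among the 9 with a mean log2 CPM of at least 6, a setting added after the data were seen, the median was −0.38, and the list passed as lower (camera adjusted p = 0.037). Members were Glul at −0.48 and Kcnj10 at −0.77 (adjusted p = 0.271 for both), Gpr37 at 0.42 (0.457) and the filament protein Vim at −0.44 (0.512). Vascular and pericyte markers had a median of −0.09 over 5 records (camera adjusted p = 0.985), with Vtn, which rods also express, at 0.43 (adjusted p = 0.4). Astrocyte and oligodendrocyte markers had −0.15 over 5 records (camera adjusted p = 0.25). Lists with fewer than 5 records were not tested. Their medians were 0.15 over 2 records of retinal pigment epithelium, −1.27 over 4 of microglia and macrophages and −0.18 for 1 of red blood cells, and 0 records of lens crystallins were measured well enough to test. None of the members of these lists passed.

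Interferon response genes were lower as a list, with a median log2 fold change of −2.84 over 6 records, or −2.75 with the 2 records without shBCOR counts at their bound (camera adjusted p = 0.0372; adjusted p = 0.613 with an estimated correlation). No member passed, over all records or adjusted over the list alone. Ifit3 had 20 and 19 counts in the controls and 0 in both shBCOR libraries, at least 8.35-fold lower (adjusted p = 0.586), and Gbp2 had 20 and 14 and likewise 0, at least 7.28-fold lower (0.606). B2m, a part of class I histocompatibility molecules, had −2.63 (adjusted p = 0.746) and the RNA sensor Ddx58 had −3.05 (0.799). The remaining 2 members, which held more counts, were not lower: H2-D1 had 0.24 (adjusted p = 0.984) and Stat2 had 0.50 (0.833). The call ended when any of the 4 libraries was left out (camera adjusted p from 0.157 to 0.588), and with a filter of 1 CPM in 2 libraries (0.0749). At equal depth 4 records remained, too few to test, with a median of −1.30.

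Lists of chromatin, growth and stress did not pass as groups, and none of their members passed. Genes of the BCOR complex had a median log2 fold change of −0.03 over 9 records, of which 7 were negative (camera adjusted p = 0.523). Among them Rybp had 0.96 (adjusted p = 0.509) and Pcgf1 −1.68 (0.631). The record of Bcl6 tested, a gene with 2 records, had 13 and 20 counts in the controls and 0 in both shBCOR libraries, at least 7.07-fold lower (0.606). Polycomb complex genes had a median of 0 over 13 records (camera adjusted p = 0.902), with Cbx6 at −0.56 (adjusted p = 0.402). Of the Polycomb-silenced developmental regulators, 1 record was tested, at −0.34. Retinal progenitor genes had −0.39 over 14 records (camera adjusted p = 0.173), with Six3 at −1.91 (adjusted p = 0.447) and Sox11 with 52 and 21 counts in the controls and 0 in both shBCOR libraries, at least 15.6-fold lower (0.456). Cell cycle genes had 0.08 over 13 records (camera adjusted p = 0.269), with Rrm1 at 0.70 (adjusted p = 0.431) and Mcm3 at 2.38 (0.553). Retinal stress and gliosis genes had −0.52 over 11 records (camera adjusted p = 0.263), p53 targets and apoptosis genes −0.47 over 8 (0.269), immediate early genes −0.50 over 13 (0.145) and unfolded protein response genes 0.06 over 11 (0.998), with the chaperone Hsp90b1 at 0.33 (adjusted p = 0.321). Immediate early genes passed as lower without shBCOR replicate 1 (camera adjusted p = 0.0249), and with fry in mixed directions they and the BCOR complex genes passed (adjusted p = 0.000582 and 0.0189).

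Metabolic lists also stayed below the threshold. Glycolysis genes had a median log2 fold change of 0.15 over 15 records (camera adjusted p = 0.173), and adjusted over the list alone 3 were higher and 0 lower. The lactate transporter Slc16a1 had 0.61 (adjusted p = 0.125), hexokinase Hk2 0.61 (0.204), the glucose transporter Slc2a1 0.58 (0.271) and Pfkfb2 0.36 (0.447). Nuclear genes of oxidative phosphorylation had a median of 0 and a mean of −0.28 over 25 records (camera adjusted p = 0.909). Cytosolic ribosomal proteins had a median of −0.05 over 39 records while camera gave the direction as up (adjusted p = 0.909). Of the mitochondrially encoded genes 0 records were listed.

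CUT&RUN gave peak lists whose replicates shared most of the peaks of the shorter list. On the autosomes and X, BCOR had 10974 peaks at E14, 5391 and 8931 at P0 and 1374 and 2502 in the adult. Otx2 had 8657 peaks at E14, 22194 and 25324 at P0 and 7320 and 14950 in the adult. At P0, 88.9% of the BCOR peaks of the shorter list overlapped a peak of the longer list (95% Wilson interval 88.1 to 89.8%), and 84.5% of the Otx2 peaks did (84.1 to 85.0%). In the adult these shares were 77.8% for BCOR (75.5 to 79.9%) and 93.8% for Otx2 (93.3 to 94.4%). Random placement gave 0.0793 to 0.959% (permutation p = 0.0099 for each, the smallest that 100 placements allow). Counted on the longer list, the shares were 52.8 and 73.9% at P0 and 42.4 and 45.0% in the adult, for BCOR and Otx2. The replicates shared 4708 BCOR and 18615 Otx2 regions at P0, and 1059 and 6716 in the adult. At E14 there was no replicate.

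The overlap of BCOR and Otx2 regions addressed whether the 2 proteins lie at the same places in the genome. Most BCOR regions held an Otx2 region at each stage. At E14 this was 5663 of 10974 BCOR regions, 51.6% (95% Wilson interval 50.7 to 52.5%), where random placement gave 0.285%. At P0 it was 3169 of 4708 regions, 67.3% (66.0 to 68.6%, random placement 0.922%), and in the adult 749 of 1059, 70.7% (67.9 to 73.4%, random placement 0.328%). The one-sided permutation p was 0.0099 at each stage, the smallest it can be. Of the Otx2 regions, 65.7% held a BCOR region at E14, 17.0% at P0 and 11.1% in the adult. Between single lists of a stage this share was 14.7 to 25.6% at P0 and 8.07 to 20.2% in the adult, so its size depended on the lists. Among the adult regions with both proteins, the highest BCOR folds were at chromosome 10, 70062011 to 70062737 (mm9), with authors' BCOR folds of 31.9 and 49.0 and Otx2 folds of 9.43 and 45.3 in the replicates. A region at chromosome 11, 97176777 to 97177389, had BCOR folds of 24.4 and 30.1 and Otx2 folds of 11.4 and 31.6. The strongest adult BCOR region without a shared Otx2 region was at chromosome 11, 115397256 to 115397971, with BCOR folds of 20.6 and 30.9 and an Otx2 peak in replicate 2 alone, of fold 5.36. These regions were chosen by their folds after the values were seen.

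**Figure D3:**
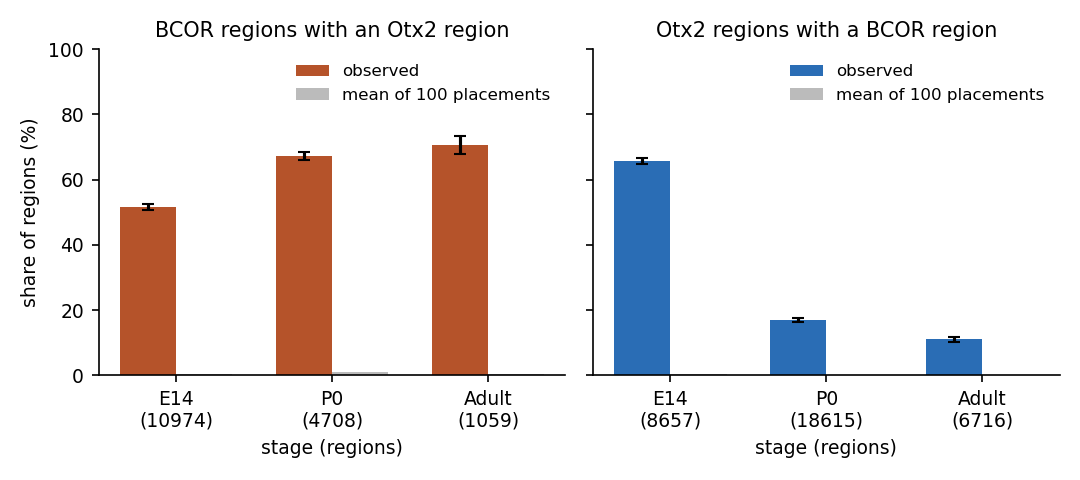
Share of BCOR regions with an Otx2 region (left) and of Otx2 regions with a BCOR region (right) at each stage, with the number of regions in brackets, 95% Wilson intervals as bars, and the mean of 100 random placements in grey. Shares of BCOR regions lie between 51.6 and 70.7%, and random placement gives less than 1%.

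The size of these shares moved with the lists used: with all lists set to the 1374 peaks of highest fold they were 47.4% at E14, 7.24% at P0 and 22.2% in the adult, and without the 533 regions that held a peak of every list the adult share was 40.8%. Within the 40017 merged regions of all lists the odds ratio of BCOR and Otx2 was 10.1 at E14 (95% interval 9.55 to 10.6), 2.68 at P0 (2.51 to 2.86) and 13.3 in the adult (11.6 to 15.2). Of these merged regions, 26295 at E14, 19959 at P0 and 33017 in the adult held no region of either factor at that stage. Regions called at other stages alone are among them and raise the odds ratio, so its size is not compared between stages.

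BCOR regions with stronger signal more often held Otx2 at E14. Ranked by the authors' fold, the share with Otx2 went from 22.2% in the lowest of 5 equal groups of BCOR regions to 86.6% in the highest. At P0 it ran from 63.2 to 70.7%, and in the adult the 5 shares lay between 68.9 and 75% with overlapping intervals. Otx2 regions of high fold more often held BCOR at every stage, from 42.7 to 90.2% at E14, 12.2 to 26.4% at P0 and 7.0 to 17.9% in the adult. Regions of high fold were also wider, with a median of 549 bp against 293 bp for BCOR at E14. In overlapping peaks the BCOR and Otx2 summits lay at a median distance of 57 bp at E14, 50 to 57 bp at P0 and 42 to 50.5 bp in the adult, against 36 to 47 bp between replicates of a factor. The trend was not tested, and E14 has 1 library of each factor. The strongest E14 BCOR regions had Otx2 folds of like size, 46.4 and 50.1 at the strongest. Of the 100 strongest E14 BCOR peaks, 59 overlapped a BCOR peak of another stage. Background limited to E14 therefore stays open as a part of the rise there.

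**Figure D4:**
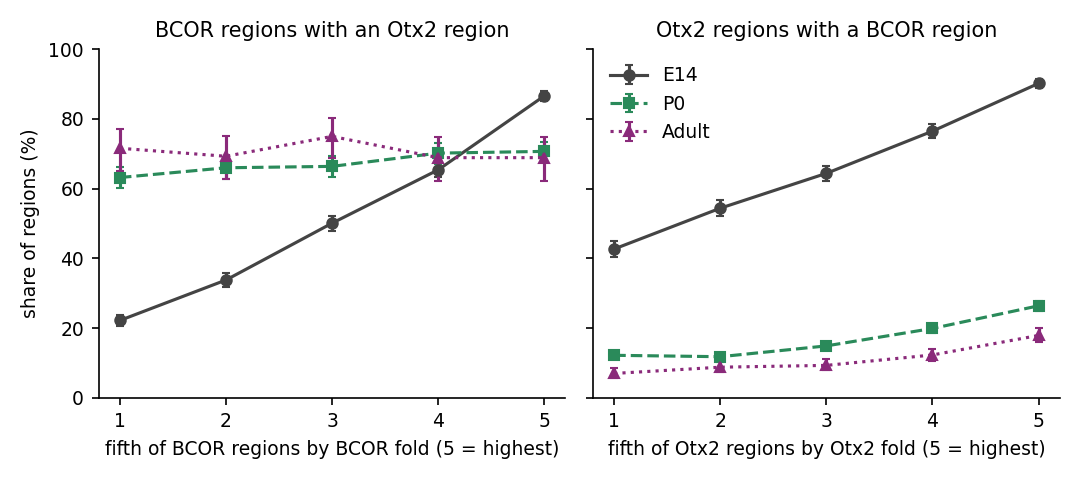
Share of BCOR regions with an Otx2 region (left) and of Otx2 regions with a BCOR region (right) by group of the authors' fold within each stage (5 equal groups, 5 the highest), with 95% Wilson intervals. At E14 the share of BCOR regions rises from 22.2 to 86.6%, and in the adult the 5 points lie between 68.9 and 75%.

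Between stages, most BCOR regions of a later stage overlapped a region of an earlier stage. Of 1059 adult BCOR regions, 831 (78.5%; 75.9 to 80.8%) overlapped a P0 region and 940 (88.8%; 86.7 to 90.5%) an E14 region, and of 4708 P0 regions 4100 (87.1%; 86.1 to 88.0%) overlapped an E14 region. Random placement gave 0.212 to 0.477% (permutation p = 0.0099 for each). In the other direction 37.8% of the E14 BCOR regions were found at P0 and 8.57% in the adult, where P0 and adult regions had to be in both replicates while E14 had a single list. Against each replicate alone these shares were 39.6 and 60% at P0 and 10.4 and 17.0% in the adult. Among 11633 merged BCOR regions 6710 were found at E14 alone, 3274 at E14 and P0, 814 at all 3 stages, 595 at P0 alone and 106 in the adult alone. The same difference in rules enlarges the class of E14 alone. Of 6716 adult Otx2 regions, 63.5% were found at P0 and 35.3% at E14, and 35.4% of the P0 regions were found at E14, while 77.0% of the E14 regions were found at P0. Among 22933 merged Otx2 regions 10041 were found at P0 alone, 4261 at E14 and P0, 2391 in the adult alone, 2324 at all stages and 1931 at E14 alone. A region at chromosome 5, 133018893 to 133020258 (mm9), among the strongest P0 BCOR regions with folds of 45.5 and 56.4, had a fold of 12.8 at E14 and no peak in the adult lists. Lists of unequal length favour such nesting: at equal length 40.3% of the adult BCOR regions were found at P0 and 43.7% at E14, 46.4% of the P0 regions at E14, and for Otx2 the shares were 21.4, 8.43 and 20.6%. The adult BCOR and the E14 lists also admitted larger q-values than the others, and without P0 replicate 1 the adult share at P0 was 88.7%.

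**Figure D5:**
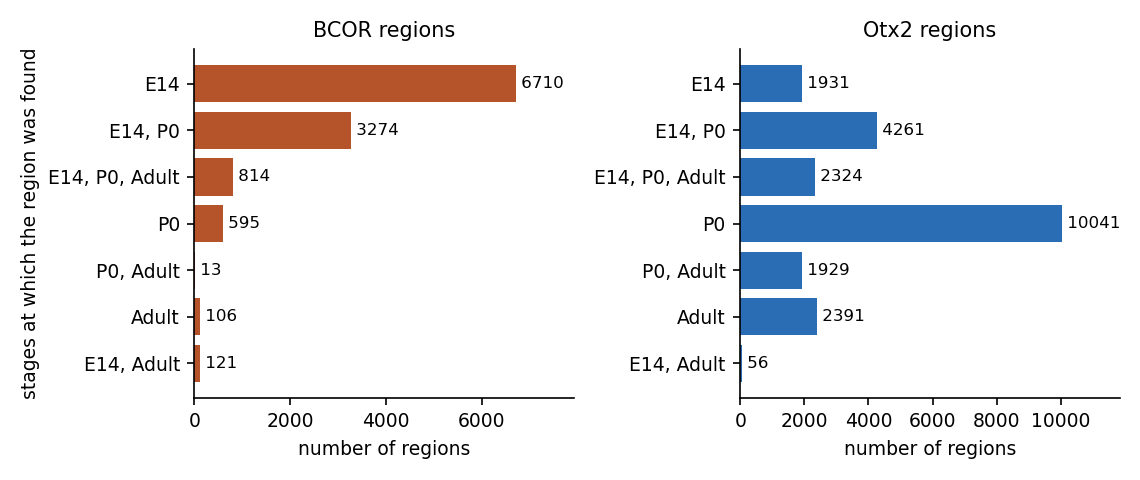
Number of merged BCOR regions (left) and Otx2 regions (right) by the stages at which they were found. The largest class of BCOR regions is E14 alone (6710) and that of Otx2 regions is P0 alone (10041).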

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

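No test was run for the counts given here, and they were looked at after the data were seen. All 10 CUT&RUN lists held peaks outside the autosomes and X, on the Y chromosome, the mitochondrial genome or unplaced sequences of mm9, which the comparisons left out. At E14 there were 149 such peaks for BCOR and 83 for Otx2. At P0 there were 19 and 43 for BCOR and 42 and 55 for Otx2, in replicates 1 and 2. In the adult there were 29 and 21 for BCOR and 24 and 36 for Otx2. Peaks on the mitochondrial genome made up 7 in each E14 list, 0 in both P0 BCOR lists, 12 and 10 in the P0 Otx2 lists, 5 and 1 in the adult BCOR lists and 1 in each adult Otx2 list. No control library without a specific antibody was analysed here, so the level of such peaks with no factor bound is unknown.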

How the results depend on the processing

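Among the alternatives given here, the gene span offset, equal depth, the sums per gene, the restriction to well-measured records, the equal-length lists, the limit of 0.05 on q, the lists without regions found in all 10, and the further settings for P0 BCOR and Otx2 regions between stages were chosen after the data were seen. The edgeR count of 7 records (3 higher, 4 lower) was the same with RLE or upper quartile scaling, a filter of 1 CPM in 2 libraries, no robust fit, equal depth and sums per gene. DESeq2 called 405 (195 higher, 210 lower), 44 of them at 0 in both libraries of a group. Without a filter on low counts 197 passed (75 and 122), at an adjusted p under 0.1 42 passed (15 and 27), and with adjustment over records with a mean log2 CPM of at least 6, 45 passed (23 and 22, 6 of the 7 among them). A fold of at least 2 left 4 (0 and 4), and the gene span offset left 2 (1 and 1). Leaving out single libraries gave 5 to 534 records, 0 to 204 higher and 4 to 362 lower. The high counts came without shBCOR replicate 1 (526) or 2 (534), where the lone shBCOR library is assumed to vary like the controls, which differed less from each other. With the replicate number as a block 45 passed (13 and 32), with the 7 among them. Whether the numbers pair the libraries is not stated. The replicate differences of the groups correlated at −0.00521 across records, which gave no sign of pairing but cannot exclude it. The block changed no list call but that of interferon genes (camera adjusted p = 0.088). For the other differences between settings the cause was not tested.

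Bcor lay between −6.58 and 0.34 with single libraries left out, the former fitted to a shBCOR library with 0 counts, at 0.13 without control replicate 1 and 0.34 without shBCOR replicate 1, and the low counts of its record limit this value. Of 97 refits of the 7 called records 86 kept the call and 11 lost it with the direction unchanged, and of 48 other named records 41 passed under some alternative and 0 changed direction. The 6 gene list calls became 0 with an estimated correlation and 3 with fry in a single direction, and 2 to 6 with single libraries left out, 2 to 4 of them among the 6. Of the lists below the threshold, Müller glia markers passed among well-measured records (adjusted p = 0.037), immediate early genes without shBCOR replicate 1 (0.0249), and immediate early, BCOR complex, and astrocyte and oligodendrocyte genes with fry in mixed directions (0.000582, 0.0189 and 0.0284). Lists with too few records in the full comparison also passed with single libraries left out, retinal pigment epithelium markers as higher without shBCOR replicate 1 (0.0249) and microglia markers as lower without shBCOR replicate 2 (0.0321). The outer segment call held in 12 of 13 alternatives, the rod call in 10 of 13, ganglion and horizontal in 9 of 12, amacrine in 8 of 12, bipolar in 7 of 13 and interferon in 4 of 11.

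The replicate shares of peaks (88.9% for P0 BCOR, 84.5% for P0 Otx2, 77.8% for adult BCOR and 93.8% for adult Otx2) were, in that order, 70.1, 73.9, 65.1 and 69.6% with a reciprocal overlap of 50%, 85.7, 86.8, 75.4 and 94.8% in the upper 50% by fold, 52.8, 73.9, 42.4 and 45.0% of the longer list, and 69.5, 82.0, 58.6 and 77.9% at equal length. The cause was not tested. All shares of BCOR regions with Otx2 stayed above random placement under every alternative run. So did the shares of adult regions found at P0 or E14 and of P0 regions found at E14. For shares in the other direction between stages no alternative was set against random placement. Not run were the fit without mitochondrial genes, since 0 were listed, and the promoter, transcription start and motif comparisons, which need a genome of build mm9. With 2 libraries per group and their spread, 3.5% of simulated 2-fold changes were recovered, so most changes of that size were out of reach; the share of this due to depth was not tested, and depth is unknown for the peaks.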

Other observations

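The tests of gene lists against each other, of equal depth on the lists and of lost records with a lowered minimum were chosen after the results were seen, as were all the genes and regions named here by their values. Records detected in both controls and in neither shBCOR library outnumbered the reverse. There were 57 records at 0 in both shBCOR libraries and at 20 or more in both controls, and 7 the other way. Some of the 57 belong to genes with several records, such as Ddx42 with 5 and Smarca1 with 4. A lost record is therefore not always a lost gene. Cd24a, a cell surface glycoprotein of neurons, had 123 and 103 counts in the controls and 0 in both shBCOR libraries, at least 48.4-fold lower. C1ql1, a synaptic organiser, had 77 and 57 against 0 and was at least 28.7-fold lower, and Cacng2, a subunit of AMPA receptors, had 83 and 49 against 0 and was at least 28.3-fold lower. None of these passed over all records in edgeR.

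Single regions of the peak lists stood out by their folds (mm9, the authors' values). Among adult BCOR regions absent at E14 and P0, the strongest lay at the strongest adult Otx2 regions. At chromosome 1, 89699885 to 89700497, BCOR had folds of 14.1 and 14.9 in the adult replicates and Otx2 had 148 and 393. At chromosome 2, 31221266 to 31221593, the values were 13.7 and 27.6 for BCOR and 175 and 271 for Otx2, and at chromosome 19, 53881144 to 53881680, they were 12.8 and 15.0 for BCOR and 160 and 255 for Otx2. These places had Otx2 peaks at P0 with folds of 19.7 to 50.4. At E14 the highest BCOR folds lay at places with an Otx2 fold of like size. At chromosome 6, 103599044 to 103599286, they were 46.4 and 50.1, and neither protein had a peak there at P0 or in the adult. Of the 100 strongest E14 BCOR peaks, 99 overlapped an E14 Otx2 peak and 59 overlapped a BCOR peak of another stage, while all 100 of the strongest P0 BCOR peaks of each replicate did the latter.

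The lower inner neuron markers beside higher rod and outer segment lists may reflect a different mix of sorted cells. A smaller share of every other cell type would lower all their markers alike. Over all records this is argued against for ganglion and horizontal cell markers, with a mean log2 fold change of −1.39 (SD 1.54, 12 records). Müller glia markers had −0.18 (SD 0.45, 17 records, two-sided permutation p = 0.00383). With a mean log2 CPM of at least 6 the medians were −1.72 over 3 records and −0.38 over 9. The means, which the test compared, were −1.08 (SD 1.14) and −0.22 (permutation p = 0.0501). Of these 3 ganglion and horizontal cell records, the neurofilament chains Nefh and Nefl were lower. The remaining record, of another gene, was not. Nefm, with a mean log2 CPM of 5.98, lay just below this limit. Among well-measured records the difference therefore rests on Nefh and Nefl. For bipolar cell markers a smaller share of every other type cannot be told apart. Their mean of −0.61 differed from that of Müller glia markers over all records (permutation p = 0.0196). Among the well-measured the medians were −0.40 and −0.38, and the means that the test compared were −0.46 and −0.22 (permutation p = 0.261). Microglia markers were lower too (median −1.27 over 4 records). A smaller carry-over of unlabelled cells born before birth, alike for all of them, would lower cone genes as well. Their mean was 0.02 (SD 0.57, 13 records, permutation p = 0.00523 against ganglion and horizontal cell markers). Among 5 well-measured cone records the median was −0.31. Their mean was −0.14, against −1.08 for the well-measured ganglion and horizontal cell markers (permutation p = 0.161 for the means). Cone genes went both ways, with 6 records positive and 7 negative. Kcnv2 had 0.54, while Opn1sw and Gnb3 had −0.31 and Opn1mw −0.72, so this carry-over cannot be told apart here. Genes within a list are not independent, so these p-values are too small, and either mix could still be a part of the difference. Lower depth of the shBCOR libraries is argued against by the calls at equal depth, where 5 of the 5 rod, outer segment, bipolar, amacrine, and ganglion and horizontal lists passed with the preset correlation (adjusted p = 0.613 with an estimated correlation for each at full depth), with medians of 0.32, 0.42, −0.46, −0.79 and −1.72, while fewer inner neurons alone, lower expression within them and an effect of BCOR on either remain open and untested, and the knockdown could not be checked.

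The excess of records lost from both shBCOR libraries may come from their lower depth. With the libraries grouped by replicate number the numbers were 9 and 9, and in the remaining split 8 and 4. At equal depth with the minimum kept at 20 counts, 16 records were lost and 6 gained, a ratio of 2.67 (exact binomial p = 0.0525), from which depth and the knockdown cannot be told apart, since thinning also takes control counts under 20. With the minimum lowered to 13, as thinning lowers the controls, 59 were lost and 11 gained, a ratio of 5.36 (exact binomial p = 4.47e-09). The other splits gave 21 and 17, and 13 and 13. The binomial p-values count records of the same libraries, which are not independent, and measure no spread between replicates. The ratio itself, beside the other splits, argues against total counts as the whole cause. Fewer distinct molecules in the shBCOR libraries, a different mix of cells and an effect of the knockdown remain open and untested.

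The overlap of BCOR and Otx2 regions may arise from places that give peaks with any antibody. Regions with a peak in all 10 lists do not explain all of it, since without them the share was at least 40.8% at each stage. The highest of 100 random placements was at most 1.22%. In the adult, however, they held much of the overlap: without them 522 of 1059 BCOR regions remained, and the share fell from 70.7 to 40.8%. Background limited to a stage is not covered by this and stays open. This holds above all at E14, where the strongest BCOR regions had Otx2 folds of like size. Peak-rich neighbourhoods are also argued against, since a move of the BCOR regions by 10 kb lowered the shares to 0.715, 1.87 and 1.94%, at least 36-fold less. Open chromatin that the nuclease reaches whatever the antibody cannot be told apart from shared binding. The adult odds ratio among the regions of all lists was 13.3, but more open places would raise it too. Regions called at other stages alone also raise it, and no list without a specific antibody was analysed here. An antibody that also takes CRX was not tested.

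A hypothesis was that adult BCOR regions not found at P0 lie at Otx2 regions that also appear after P0. Of 228 such BCOR regions, 32 (14%) held an Otx2 region of the adult alone, against 16 (1.93%) of the 831 found at P0, an odds ratio of 8.32 (95% interval 4.47 to 15.5, two-sided Fisher's exact p = 6.22e-12). With lists of equal length it was 12.6 (5.44 to 29.2). Of the P0 BCOR regions, 67.3% overlapped a P0 Otx2 region, and such places cannot hold an Otx2 region of the adult alone. An odds ratio above 1 thus follows in part from that overlap. At equal length that share was 7.24%, but there the shares with any adult Otx2 region, given below, already differed. The p-value counts regions, which are not replicates. The association therefore cannot decide the hypothesis, which would cover a part of these regions at most. Most of the 228 held no Otx2 region of the adult alone, as did most at equal length, where 19.2% of 479 held one. The strongest regions named above had Otx2 peaks at P0. The share with any adult Otx2 region also moved with the lists, at 79.8% of the 228 against 68.2% of those found at P0, and at equal length 32.6% of 479 against 6.79% of 324. A rise in openness of these places could give the same.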
